A study of Homo sapiens with 6 samples.

How the data were processed

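Total RNA from SK-N-BE(2) cells was sequenced as 6 libraries, 3 with a control hairpin and 3 with a MYT1 hairpin. The labels' protocols name a NEBNext Ultra RNA kit and do not state a strand-specific protocol. The authors deposited 1 table of FPKM, 1 column per library. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and the build hg38 were used. The annotation, strand setting and filters are not given in the sources used here.

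The deposited FPKM table holds 32434 gene IDs, of which 32301 (99.59%) were found in GENCODE 29, the source of symbols, types and positions. FPKM times the union exon length of a gene was a whole multiple of 1 step per library, within 0.01, in all 6 libraries for 95.4% of these IDs (30809). The step gave the fragments behind each value, 18.16 to 21.68 M per library in total. Lengths of the other IDs differ from GENCODE 29, so totals are approximate. The library size used in the FPKM was not this total: fragments exceeded it by 0.42 to 1.24% in shNC and by 1.71 to 2.72% in shMYT1. Over the 22101 genes above 0 in every library, the median ratio to the mean library agreed between libraries to within 7e-08%. The deposited values thus already carried a median-of-ratios scaling, a step no label or header records, and were used as they are. A level of 3 fragments on 1 kb of exon equals 0.140 to 0.170 FPKM. Such floors cover counting error only.

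Genes with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 (R 4.3.3) on log2(FPKM + 1), with a variance trend, two-sided, and Benjamini-Hochberg adjustment. A gene passed at adjusted p under 0.05. Fold changes are shMYT1 minus shNC on the log2(FPKM + 1) scale, which understates changes of low genes. The 38 gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Lists with at least 5 tested genes (35) were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. The lists hold 1049 entries, 1005 of them found in the table.

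The rule named MYT1, then the 10 largest rises and 10 largest falls among protein-coding genes past the threshold with no overlap between groups and a mean of at least 5 FPKM in the higher group. It then named up to 4 passing members per described list with the largest absolute change, or the 2 highest members where none passed. RARA, RARB, CYP26A1, CYP26B1, CRABP2, DHRS3, MYCN, TH, GAP43 and NEFM were always named. Some genes that the rule selects are not reported here. Of the 162 genes the rule selects, 43 share exon bases with a gene on the opposite strand and 7 with one on the same strand. Fragments there cannot be assigned with certainty. CACNA1H, IGF2, TGM2, RARA, DBH, CCND1, NRP1, NEFM and MYCN are among the former.

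Fold changes of genes with a mean of at least 3 FPKM, limited to 0.6 either way, were divided into segments of at least 20 genes by binary segmentation. The threshold was the 95th percentile of 1000 permuted gene orders. A segment was called shifted when its median differed by at least 0.1 from that of all genes. This search was chosen after the data were seen.

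The methods were tested on simulated data. A first simulation with an assumed dispersion missed its set limit for recovered genes, after which the dispersion was estimated from the data and the limits were changed. Counts for 14070 genes were drawn with the real means and library sizes and 1 dispersion (0.00131) for all, and 13830 were left unchanged. Real genes need not share 1 dispersion, so the shares recovered and falsely called need not hold for them. For the 3 against 3 comparison, limma recovered 19 of 50 genes changed 1.25-fold, 38 of 50 changed 1.5-fold, 46 of 50 changed 2-fold and 50 of 50 changed 4-fold. Of its 180 calls, 9 were unchanged genes. Camera found the 1 raised list and called 0 of 36 unchanged ones. Genes were drawn independently, so this leaves out correlation between list members, which was estimated at up to 0.397 in the real lists. It says nothing of false calls among lists of correlated genes. Segmentation found 0 shifted segments in 1 shuffled gene order and 1 after 100 neighbouring genes were raised by 0.2.

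Replicates of a group differed by more than counting noise: the chi-square per gene between pairs, over genes with at least 20 fragments in the pair, was 1.91 to 3.28. None were merged. Alternatives varied the pseudocount, filter, scaling, variance model, gene types and threshold, added the replicate number as a block, and left out each library in turn. Added after the data were seen were voom on recovered fragments, thinning to equal depth, removal of a running median over 50 neighbouring genes, omission of the shifted segments, and scaling to total fragments or without mitochondrial genes.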

Results

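RNA sequencing was used to compare SK-N-BE(2) cells, a human neuroblastoma cell line, carrying a short hairpin RNA against MYT1 (shMYT1, 3 libraries) with cells carrying a control hairpin (shNC, 3 libraries). MYT1 encodes a zinc-finger transcription factor of developing neurons. The series title places MYT1 between neuroblastoma differentiation and retinoic acid signalling, and the comparison asks which transcripts differ when MYT1 is lowered. The labels describe a lentiviral knockdown with 24 h of infection and 48 h of puromycin, while the genotype and design fields say knockout. It is described here as a knockdown. The deposited values give 21.08 to 21.68 M fragments per shNC library and 18.16 to 20.3 M per shMYT1 library. Between 27071 and 27812 of 32434 gene IDs were above 0. Correlations of log2(FPKM + 1) across genes were 0.987 to 0.989 within groups and 0.979 to 0.981 between groups. The first principal component held 44.6% of the variance and separated the groups. No label says that the replicates were separate cultures, so p-values measure the spread between these samples only.

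MYT1 itself (ENSG00000196132, chromosome 20, 64102394 to 64242253, plus strand, hg38) was measured at 5.34 ± 0.34 FPKM (SD, n = 3) in shNC and 4.23 ± 0.12 FPKM (SD, n = 3) in shMYT1. This is a difference of -20.8% in the means. All 3 shMYT1 libraries lay below all 3 shNC libraries. The log2 fold change was -0.28 (SE 0.05, 95% interval -0.40 to -0.16, limma adjusted p = 0.0102). The exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. Between 470 and 791 fragments per library lay behind these values.

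Of 14106 genes tested, 1683 rose and 1737 fell in shMYT1 cells (limma, adjusted p under 0.05), 24.2% of the genes. Most shifts were small: the median absolute log2 fold change of these genes was 0.27, and 86.0% of them moved by under 0.5. Only 33 genes rose and 38 fell by at least 1 on the log2 scale. In 42.3% of tested genes the groups did not overlap, against 10% by chance. The number of genes past the threshold was 2195 without shNC replicate 1, 2038 without shNC replicate 2 and 2196 without shMYT1 replicate 1. These omissions each moved it by over 1.5 times. It was 3048 without shNC replicate 3, 2632 without shMYT1 replicate 2 and 2298 without shMYT1 replicate 3. Each of these fits has fewer samples, so the falls cannot be laid to particular libraries. When each library was rescaled to the same FPKM total, 36.4% of the genes past the threshold were higher in shMYT1, against 49.2% as deposited.

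The largest rises under the fixed rule were in NPW, a neuropeptide gene, ODAM, CRABP2, SST, SCGN, IGF2, CACNA1H, BCHE, ZIC2 and CXCL12. NPW went from 1.42 ± 0.10 to 6.30 ± 0.51 FPKM (SD, n = 3 in each group; log2 fold change 1.59). SST, which encodes somatostatin, went from 6.92 ± 0.67 to 19.2 ± 0.61 FPKM (SD, n = 3 each). SCGN, a calcium-binding protein of neuroendocrine cells, went from 11.5 to 30.7 FPKM. IGF2, an insulin-like growth factor, went from 1.55 to 5.41 FPKM. The adjusted p of the 10 genes lay between 1.02e-06 and 0.000565. The largest falls were in DPT, KRT17, LIX1, SHD, NR0B1, TMPRSS15, GPC3, PROK2, STMN4 and GALNT13. DPT, which encodes the matrix protein dermatopontin, went from 19.5 ± 0.59 to 2.10 ± 0.22 FPKM (SD, n = 3 each; log2 fold change -2.73). The keratin gene KRT17 went from 26.6 ± 0.32 to 3.77 ± 0.13 FPKM (SD, n = 3 each; log2 fold change -2.53). STMN4, a stathmin of neurons, went from 15.0 to 5.47 FPKM, and NR0B1, a nuclear receptor, from 11.1 to 3.01 FPKM. The adjusted p of the 10 falls lay between 6.23e-07 and 0.000208. ODAM, ZIC2, SHD and STMN4 lie in the chromosome segments described further on.

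**Figure D1:**
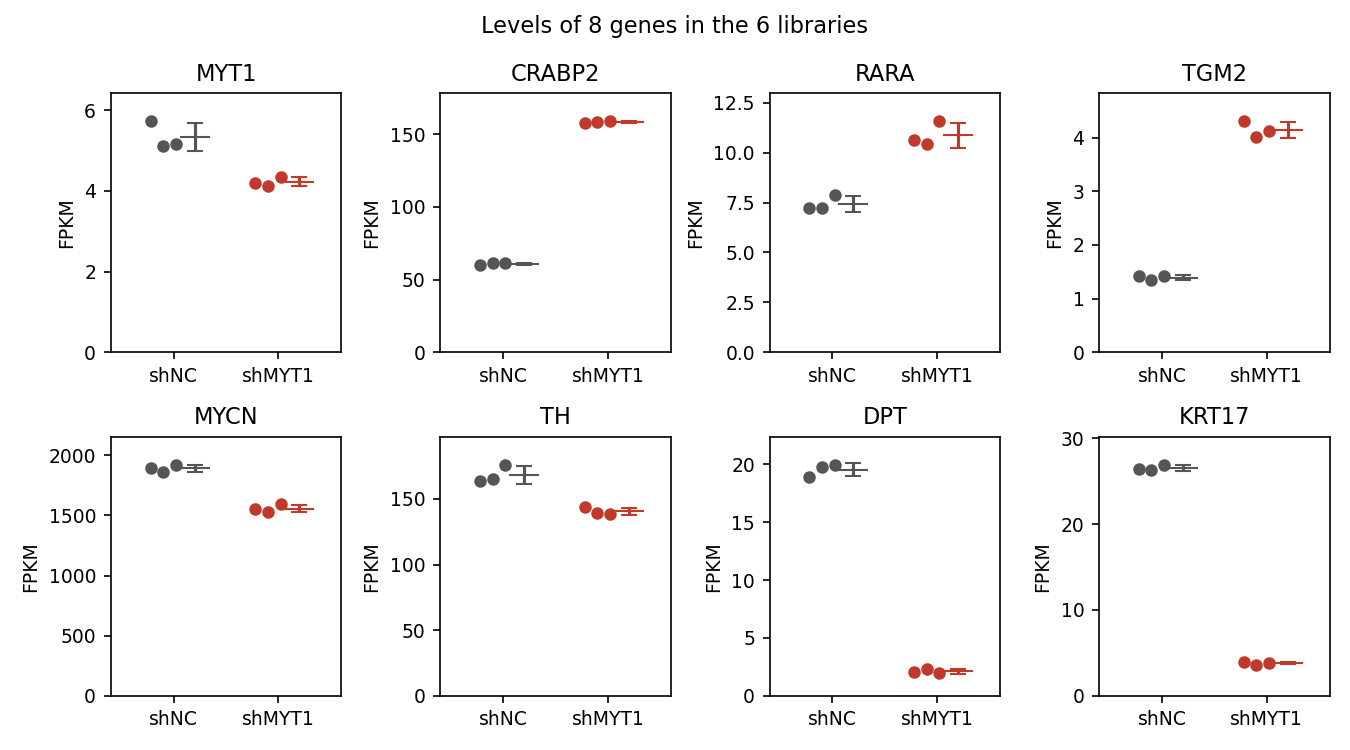
FPKM (y axis, from 0) of 8 genes in the 3 shNC and 3 shMYT1 libraries, with points for libraries and a bar for the mean ± SD. In all 8 genes the groups do not overlap: CRABP2 averages 61.0 against 158 FPKM and DPT 19.5 against 2.10 FPKM.

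Retinoic acid genes moved in both directions. CRABP2, which encodes a cellular retinoic acid binding protein, rose from 61.0 ± 0.62 to 158 ± 0.67 FPKM (SD, n = 3 each), 2.60-fold, with a log2 fold change of 1.36 (SE 0.02, limma adjusted p = 1.02e-06). TGM2, the tissue transglutaminase gene, rose from 1.39 to 4.15 FPKM. PLAT, a gene of the chromosome 8 segment that rose against its neighbours, went from 8.31 to 11.4 FPKM and TSHZ1 from 5.09 to 6.61 FPKM. Among the 14 tested members of the 38 retinoic acid target genes listed, 6 rose, 3 fell and 5 did not pass, with 6 and 3 adjusted over the list alone. The list was not past the threshold as a whole (camera adjusted p = 0.0785, and adjusted p = 0.356 with an estimated correlation), and passed at 0.046 without shMYT1 replicate 2 and at 0.023 with voom, a setting added after the data were seen. RARA, a retinoic acid receptor, rose from 7.45 ± 0.40 to 10.9 ± 0.62 FPKM (SD, n = 3 each; log2 fold change 0.49, limma adjusted p = 0.00140). RARB was at 0.51 and 0.33 FPKM, under the filter, with limma adjusted p = 0.197 in a fit without it. CYP26B1 and CYP26A1 lay far below, and DHRS3 near, the floor of 0.140 to 0.170 FPKM that 3 fragments give on 1 kb of exon. That floor is lower for genes with more exon bases. DHRS3 averaged 0.0986 FPKM in shNC and 0.178 FPKM in shMYT1 (limma adjusted p = 0.328 in the fit without the filter). CYP26B1 averaged 0.00317 and 0.0146 FPKM, and CYP26A1 was listed at 0 in every shNC library. Among 16 tested genes of retinoid receptors, corepressors and metabolism, 3 rose and 4 fell, against 4 and 4 adjusted over the list alone (camera adjusted p = 0.708). In that list the coactivator gene NCOA2 fell by 0.48 (log2 scale) and RDH10, a retinol dehydrogenase gene, rose by 0.32. Both lie in the chromosome 8 segment.

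Genes of the noradrenergic neuroblastoma state did not move one way. Of 25 tested transcription factors of this state, 7 rose and 7 fell, against 8 and 11 adjusted over the list alone (camera adjusted p = 0.558). TBX2 went from 33.6 to 48.4 FPKM and DACH1 from 0.635 to 1.59 FPKM, while TBX3 went from 73.2 to 46.9 FPKM and INSM1 from 5.04 to 3.26 FPKM. MYCN fell from 1892 ± 30.9 to 1558 ± 31.9 FPKM (SD, n = 3 each; log2 fold change -0.28, limma adjusted p = 0.000969). The MYCN call was lost in the fit without a filter on low values, with adjusted p = 0.0618. MYCN shares exon bases with MYCNOS on the opposite strand, and no strand setting is stated.

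Catecholamine genes split in the same way, with 5 of 18 up and 6 down, and 6 and 7 adjusted over the list alone (camera adjusted p = 0.891). The list's median log2 fold change was -0.01 and its mean 0.12, so they differ in sign, and the test's direction was up. The vesicular monoamine transporter gene SLC18A1 went from 0.592 to 2.76 FPKM, and the noradrenaline transporter gene SLC6A2 from 10.99 to 21.5 FPKM. DBH, which encodes dopamine beta-hydroxylase, went from 5.62 to 10.5 FPKM and VGF from 72.3 to 95.1 FPKM. TH, the gene of tyrosine hydroxylase, fell from 168 ± 6.93 to 141 ± 2.78 FPKM (SD, n = 3 each; limma adjusted p = 0.00340).

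Neuronal genes also went both ways. GAP43, a growth cone protein gene, rose from 133 to 157 FPKM. NGFR, a neurotrophin receptor gene, fell from 9.09 to 5.71 FPKM. NEFM, a neurofilament gene, fell from 76.2 to 67.2 FPKM. NEFM lies in the chromosome 8 segment, and with the regional running median removed, also a later setting, its log2 fold change was -0.01 (limma adjusted p = 0.805). Of 28 tested genes of the neuronal cytoskeleton and neurite outgrowth, 8 rose and 8 fell, against 8 and 10 adjusted over the list alone (camera adjusted p = 0.783). NRCAM and L1CAM, both cell adhesion genes, rose by 0.48 on the log2 scale, and STMN4 fell by 1.31. Of 26 synaptic vesicle genes, 3 rose and 8 fell, against 4 and 8 adjusted over the list alone (camera adjusted p = 0.213). Of 12 neuronal RNA-binding and proneural genes 4 rose and 4 fell, against 4 and 6 adjusted over the list alone, with a median of -0.12, a mean of 0.001 and a test direction of down (camera adjusted p = 0.675).

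More genes rose than fell in 7 groups past the threshold at the preset correlation. Of 21 tested marker genes of the mesenchymal neuroblastoma state, 13 rose and 2 fell, against 14 and 2 adjusted over the list alone (camera adjusted p = 3.14e-05, and adjusted p = 0.356 with an estimated correlation). SOX9 went from 1.89 to 4.45 FPKM, ANXA1 from 0.977 to 2.70, CYR61 from 4.74 to 9.43 and FN1, the fibronectin gene, from 18.1 to 31.6. Of 32 axon guidance genes, 11 rose and 2 fell, against 13 and 3 adjusted over the list alone (camera adjusted p = 0.00156, and adjusted p = 0.356 with an estimated correlation). PLXNA4 rose from 3.63 to 8.26 FPKM, EFNB2 from 4.35 to 8.61 and NRP1 from 6.67 to 11.98. EFNB2 lies in the chromosome 13 segment. Of 28 collagen and extracellular matrix genes, 12 rose and 7 fell, against 16 and 7 adjusted over the list alone (camera adjusted p = 0.0189, and adjusted p = 0.567 with an estimated correlation). MMP2 rose from 83.1 to 142 FPKM and COL5A1 from 9.73 to 15.0, while THBS2 fell from 1.95 to 0.900. The matrix list lost its call with no filter on low values (adjusted p = 0.0849) and with a minimum of 5 FPKM (adjusted p = 0.232). Beside these groups, the summed FPKM of 14 fibroblast and smooth muscle markers was 197 to 202 in shNC and 155 to 159 in shMYT1. Most of that difference lay in 1 gene, LUM, which went from 97.7 to 54.6 FPKM. In that marker list LUM and DCN fell while TAGLN and ACTA2 rose, 4 of 9 tested genes up and 3 down, against 4 and 4 adjusted over the list alone (camera adjusted p = 0.783). The 9 tested genes had a median log2 fold change of 0.09 and a mean of -0.001, which differ in sign. The summed FPKM of 12 Schwann cell precursor and glial markers was 28.4 to 29.7 in shNC and 34.1 to 35.0 in shMYT1, with 1 of 5 tested genes up and 1 down, against 2 and 1 adjusted over the list alone (camera adjusted p = 0.714).

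Changes were small in ribosomal and mitochondrial groups. Of 71 cytosolic ribosomal protein genes, 22 rose and 2 fell, against 23 and 2 adjusted over the list alone, with a mean log2 fold change of 0.10 (camera adjusted p = 7.56e-06, and adjusted p = 0.575 with an estimated correlation). RPL13A, RPS19 and RPL18 rose by 0.43 to 0.49, and all 3 lie on the long arm of chromosome 19. Of the 71 genes, 16 lie in shifted segments, and outside them 13 rose and 0 fell. Ribosomal protein genes have many near-identical pseudogenes, so their values are uncertain. The list's call was lost with quantile normalization (adjusted p = 0.0726). Of 40 nuclear-encoded oxidative phosphorylation genes, 9 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.00392, and adjusted p = 0.515 with an estimated correlation). COX6B1 and UQCRFS1, both on the long arm of chromosome 19, rose by 0.47 and 0.37, and UQCRH on chromosome 1 rose by 0.27. Of 13 mitochondrially encoded mRNAs, 3 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.0187, and adjusted p = 0.567 with an estimated correlation). These were MT-CO2, MT-CYB and MT-CO1, by 0.25, 0.17 and 0.12, and mitochondrial genes took 22.97 to 23.91% of all FPKM in shNC and 24.56 to 24.73% in shMYT1. The mitochondrial call was lost without shNC replicate 3 (adjusted p = 0.124), with no filter (0.313), on rescaling to a common FPKM total (0.0666) and with quantile normalization (0.651). The MT-CO1 call was lost when any library other than shMYT1 replicate 1 was left out (adjusted p from 0.0868 to 0.142), with the replicate block (0.112), on rescaling (0.0881), with no variance trend (0.0769), with quantile normalization (log2 fold change 0.00) and in 4 settings added later (0.0521 to 0.0655). With no filter none of the 3 mRNAs passed, with adjusted p = 0.557 for MT-CO2 and 0.221 for MT-CYB.

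Of 13 type I interferon response genes, 7 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0192, and adjusted p = 0.356 with an estimated correlation). OAS1 rose from 0.602 to 2.19 FPKM, BST2 from 3.77 to 6.69 and PARP14 from 1.97 to 3.08. BST2 lies in the shifted short arm of chromosome 19 (median log2 fold change -0.12), so it rose against its segment. Without the genes of shifted segments the list had camera adjusted p = 0.0512, and with the regional running median removed camera adjusted p = 0.0158. The call was also lost without shNC replicate 3 (adjusted p = 0.0531), with no filter (0.139) and with a minimum of 5 FPKM (0.191).

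More genes fell than rose in stress, sterol and cell cycle groups. Of 32 genes of the integrated stress response and amino acid supply, 20 fell and 3 rose, against 24 and 3 adjusted over the list alone (camera adjusted p = 7.56e-06, and adjusted p = 0.356 with an estimated correlation). ATF3 went from 3.65 to 2.06 FPKM, CBS from 16.8 to 12.1 and the cystine transporter gene SLC7A11 from 11.3 to 8.17. Of 24 cholesterol biosynthesis genes, 13 fell and 0 rose, against 14 and 0 adjusted over the list alone (camera adjusted p = 1.44e-05, and adjusted p = 0.356 with an estimated correlation). SC5D went from 34.3 to 17.7 FPKM, CYP51A1 from 3.14 to 1.63 and HMGCS1 from 39.6 to 26.2. Of 40 mitosis genes, 11 fell and 0 rose, against 16 and 0 adjusted over the list alone (camera adjusted p = 7.69e-05, and adjusted p = 0.356 with an estimated correlation). ANLN, BIRC5, KIF23 and CENPA fell by 0.22 to 0.32 on the log2 scale. Of 40 DNA replication and S phase genes, 14 fell and 5 rose, against 15 and 5 adjusted over the list alone (camera adjusted p = 0.0102, and adjusted p = 0.356 with an estimated correlation). MCM4 went from 64.7 to 47.7 FPKM, while CCNE1 went from 3.31 to 5.58 and POLD1 from 14.5 to 18.4. MCM4, CCNE1 and POLD1 lie in shifted segments, and with the regional running median removed POLD1 lost its call (log2 fold change 0.06 instead of 0.33, limma adjusted p = 0.197). Outside these segments 11 replication genes fell and 1 rose. Of 8 Wnt target genes 1 rose and 3 fell, against 2 and 3 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.328). CCND1, the cyclin D1 gene, is 1 of the 3 and fell from 260 to 186 FPKM.

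**Figure D2:**
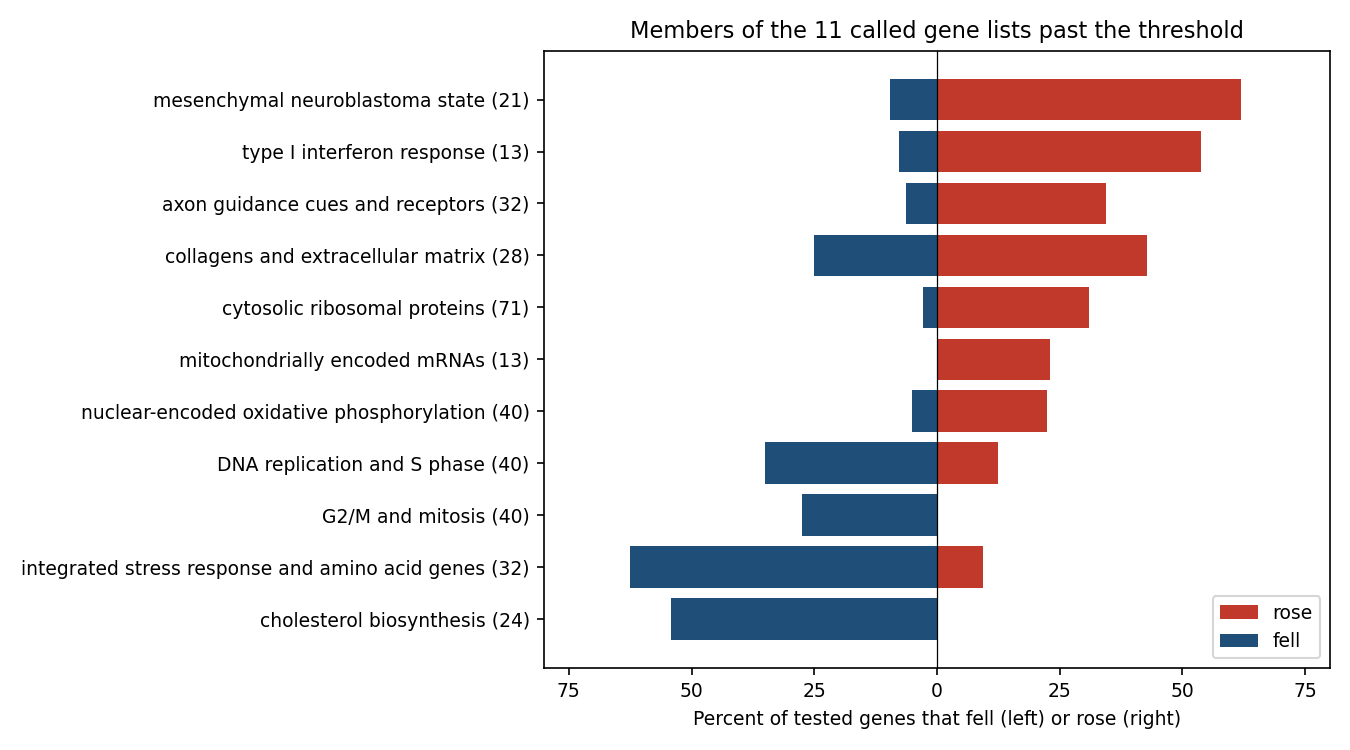
Percent of tested genes (x axis) that rose, to the right, or fell, to the left, in shMYT1 for the 11 gene lists past the threshold, with the number of tested genes in parentheses. Bars to the right are longer in the 7 lists that went up: 13 of 21 mesenchymal genes rose, and 0 of 24 cholesterol genes did.

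In all, 11 of 35 tested lists passed the threshold, 7 up and 4 down, and none of the 11 passed with a correlation estimated from the data (adjusted p 0.356 to 0.575). Of these lists, the type I interferon list alone had an estimated correlation (-0.041) under the preset 0.01, yet its unadjusted camera p rose from 0.00603 to 0.0438. Estimated correlations of the others reached 0.397, in the cytosolic ribosomal list. The losses thus cannot be laid to correlation between list members alone. With an estimated correlation, camera also uses the residual degrees of freedom of the 6 libraries, not those set by the number of genes. That alone raises p, and its share in the losses was not separated from that of correlation. The other 24 lists, among them Notch, p53, hypoxia and heat shock genes, did not pass. The hypoxia list had a median of 0.06, a mean of -0.03 and a test direction of up (camera adjusted p = 0.714). Markers of endothelial and haematopoietic cells had 0 tested genes, and epithelial markers had 1, EPCAM, at 1.36 and 1.06 FPKM.

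Genes that neighbour each other on 4 chromosomes shifted together by at least 0.1 in the median. On the long arm of chromosome 19 (29.2 to 58.6 Mb) the median log2 fold change was 0.31, and 235 of 436 tested genes rose and 1 fell. Chromosome 13 (19.6 to 114.3 Mb) had a median of 0.23, with 118 of 217 up and 5 down. Chromosome 8 from 0.2 to 134.8 Mb had a median of -0.24, with 228 of 439 down and 18 up. Chromosome 4 from 65.6 to 101.3 Mb had a median of 0.17, with 35 of 88 up and 2 down, and the short arm of chromosome 19 (0.3 to 24.1 Mb) a median of -0.12, with 124 of 476 down and 16 up. The 3 shMYT1 libraries gave medians of 0.29 to 0.34 on the long arm of chromosome 19 and -0.26 to -0.21 on chromosome 8, relative to the shNC mean. Without shNC replicate 3 the short arm of chromosome 19 had a median of -0.09, short of the 0.1 that defines a shifted segment. These segments held 11.7% of the tested genes and 22.9% of those past the threshold. Outside them, 1261 genes rose and 1377 fell. Smaller shifts lay there too, short of the 0.1 that defines a shifted segment. Chromosome 4 from 102.3 to 190 Mb had a median of -0.08, with 46 of 221 down and 12 up. Chromosome 17 from 0.1 to 68.3 Mb was at -0.07, with 120 of 673 down and 55 up. Chromosome 8 from 135.5 to 145.1 Mb was at -0.09, with 16 of 84 down and 3 up. Chromosome 1 up to 163.3 Mb was at 0.05, with 163 of 1043 up and 75 down.

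**Figure D3:**
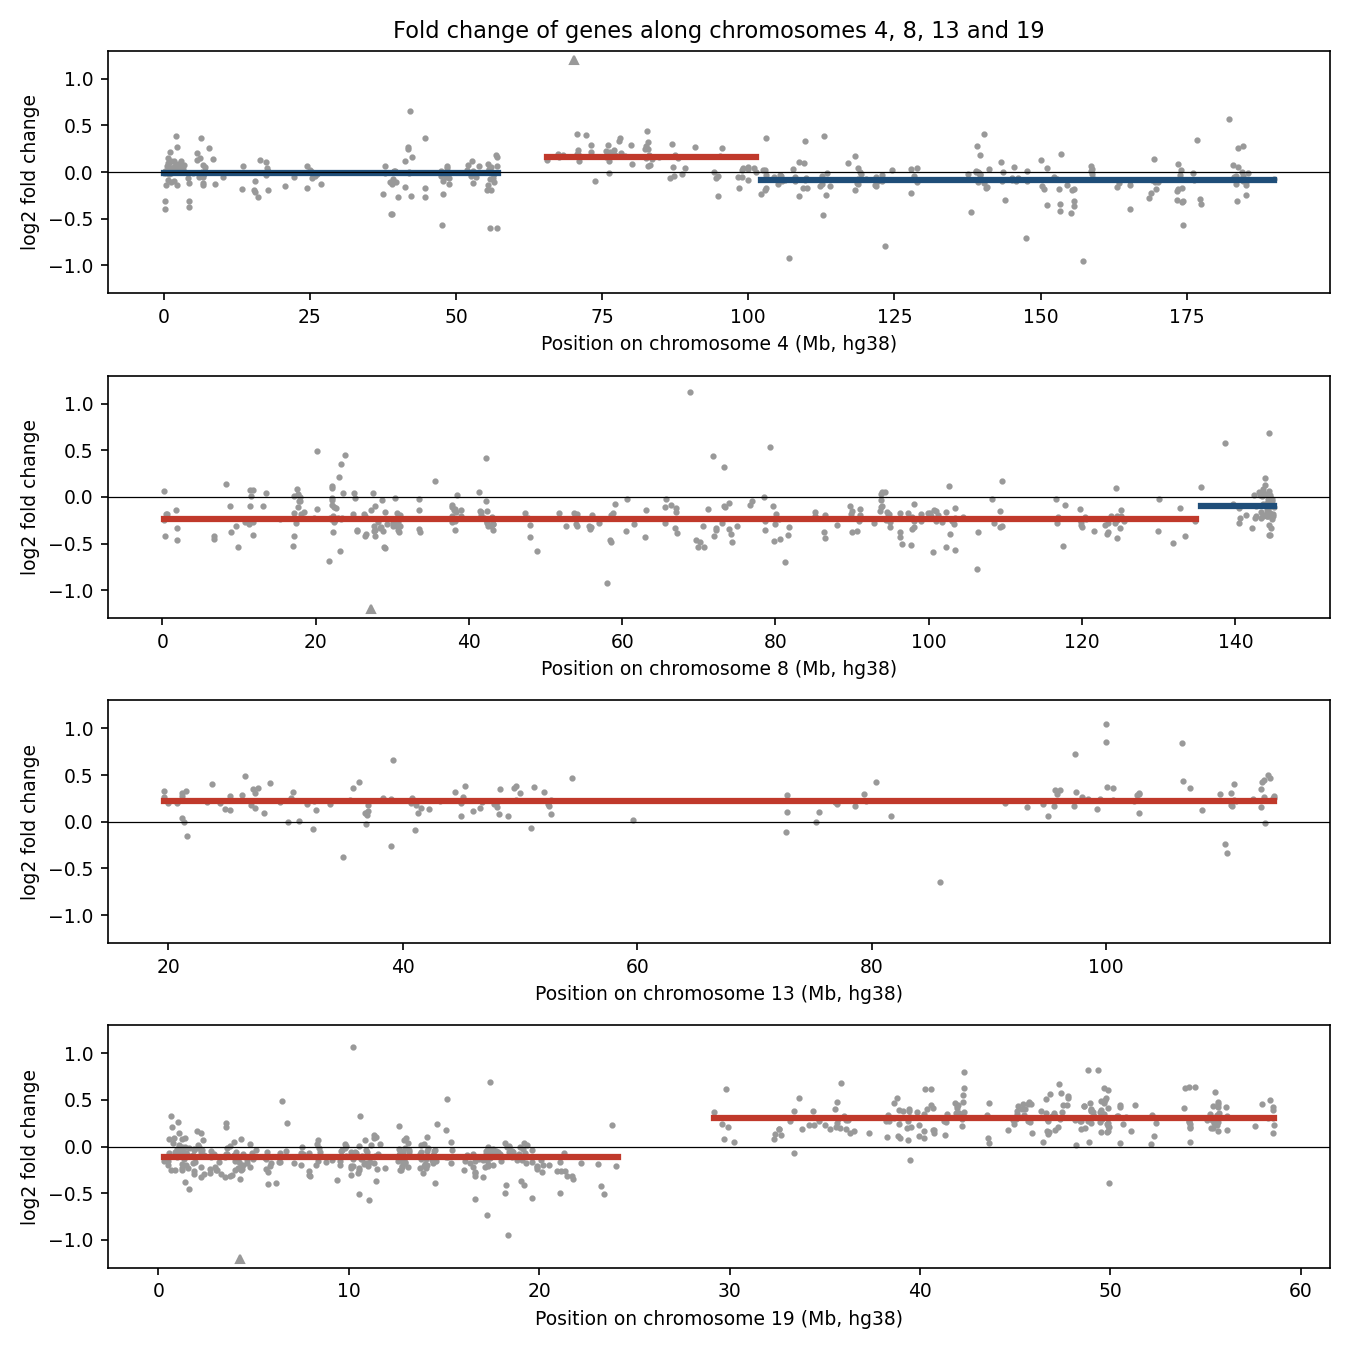
Log2 fold change of each gene with a mean of at least 3 FPKM (y axis) against its position in Mb (x axis) on chromosomes 4, 8, 13 and 19. Lines are segment medians, red where the segment is shifted by at least 0.1 and blue elsewhere, and triangles are genes beyond the axis: the long arm of chromosome 19 sits at 0.31 and chromosome 8 at -0.24.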

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

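Settings built on voom, thinning, neighbouring genes, mitochondrial genes or total fragments were chosen after the data were seen. The log2 fold change of MYT1 stayed negative and past 0.05 in each setting that gave it a value, from -0.35 to -0.23. The minimum of 5 FPKM removed MYT1, and it passes neither adjusted p under 0.01 nor a minimum change of 1. Genes past the threshold numbered 3420 (1683 up, 1737 down). A minimum change of 1 left 71 (33 up, 38 down), and adjusted p under 0.01 left 1494 (761 up, 733 down), by construction. Leaving out each library gave 2038 to 3048 genes, 1018 to 1579 up and 1020 to 1469 down, with fewer samples. Voom on recovered fragments gave 2615 down, and scaling to total fragments gave 2007. The cause was not tested further. Median-of-ratios scaling moved nothing, since the deposited values carry it, and says nothing about stability. With the replicate block 3381 genes passed (1652 up, 1729 down). Same-numbered libraries correlated at 0.033, 0.013 and 0.043, and every library correlated best with its own number. Any effect of pairing by number was thus weak, and the values cannot show whether the numbers pair cultures. Rescaling to a common FPKM total shifted the median of all genes from -0.00 to -0.04 and the share of higher calls from 49.2 to 36.4%.

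Of the gene list tests, 11 passed. With an estimated correlation, which also lowers the degrees of freedom, 0 passed. With fry, which compares no list with other genes, 21 did. Leaving out a library gave 9 to 13. Of 803 other results on single lists, 11 lost and 9 gained a call, and 20 changed sign, none of them past the threshold. The cause was not tested. With a minimum of 5 FPKM, the mean differences from other genes were -0.06 for neuronal RNA-binding and proneural regulators, 0.027 for neurotrophin and GDNF signalling, 0.021 for BMP and TGF-beta targets and -0.16 for fibroblast and smooth muscle markers. Quantile normalization gave -0.002 for the fibroblast list, voom 0.001 for noradrenergic factors and thinning 0.001 for CDK inhibitors and cyclins of G1. With the running median removed, neuronal RNA-binding genes were at -0.017, neurotrophin genes at 0.012, and the chromosome 13 segment at -0.006 by construction. Of 110 segment medians in other settings, 13 moved by more than the SD between shMYT1 libraries and 1 changed sign, and each of the 5 segments moved in at least 1 setting. With the running median removed all lay between -0.019 and 0.051, by construction. Otherwise the long arm of chromosome 19 was at 0.34 with a pseudocount of 0.1, chromosome 8 was at -0.29 on rescaling, and the short arm of chromosome 19 ranged from -0.16 on rescaling to -0.09 without shNC replicate 3. Without the shifted segments the neuronal cytoskeleton was at 0.04, neuronal RNA-binding genes at -0.033, neurotrophin genes at 0.072 and G1 genes at 0.006. Leaving out a library gave -0.012 to 0.016 for neuronal RNA-binding, -0.036 to 0.008 for neurotrophin, -0.008 to 0.013 for fibroblast and -0.014 to 0.002 for MYC target genes. Of 157 named genes, 26 lost their call in at least 1 setting and none changed sign.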

Other observations

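Some further genes were chosen after their values were seen, from no fixed list and with no test of them as a group. The somatostatin gene SST and its receptor gene SSTR1 both rose, SSTR1 from 0.396 ± 0.07 to 3.83 ± 0.31 FPKM (SD, n = 3 each; limma adjusted p = 7.38e-05). The chemokine gene CXCL12 and its receptor gene CXCR4 both rose, CXCR4 from 1.78 to 4.61 FPKM (limma adjusted p = 0.00215). The nicotinic receptor genes CHRNA3 and CHRNB4, neighbours on chromosome 15, rose from 24.2 to 38.1 and from 6.79 to 12.2 FPKM. CHRNA5 beside them was at 6.12 and 7.27 FPKM and did not pass (limma adjusted p = 0.121). ZIC2 and ZIC5, neighbours on chromosome 13, rose by 1.04 and 0.86 on the log2 scale, against 0.23 for the median of the shifted segment. LIFR, a cytokine receptor gene, fell from 8.42 to 3.20 FPKM, and PITX1, a homeobox gene, from 8.59 to 3.88 FPKM. TRAC, a T cell receptor constant segment, fell from 3.76 to 0.607 FPKM. Near MYCN, which fell by 0.28, DDX1 had a log2 fold change of 0.00 and NBAS of 0.10, neither past the threshold (limma adjusted p = 0.0801 for NBAS).

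Except for the splits of the samples, every test given here was chosen after the pattern it weighs was seen, and only the predictions on GC content, gene length and copy number were written before their tests were run. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 3420 genes and 11 lists, and 1 of the 10 splits, the real one, gave as many. The highest of the others was 1 gene and 6 lists.

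The shift of neighbouring genes on chromosomes 4, 8, 13 and 19 was weighed first. Chance order of genes is argued against: none of 1000 permuted orders gave 5 shifted segments (permutation p = 0.001, the smallest they can give), and 12 gave any. The threshold for dividing segments was itself set from permuted orders, so this p restates the calls and adds no separate support. GC content or gene length is argued against as the whole cause, since 84.2% or more of each median was left after a trend on both was removed, and 139.1% on the short arm of chromosome 19. A different DNA copy number in the 2 cultures is a candidate explanation. At least 75.8% of genes lay on the segment's side among weakly and strongly expressed genes alike, and 3 segments span whole arms. The segments were chosen by their medians, which favours such a share beforehand, and an effect of MYT1 on whole arms would give it too. The share thus cannot tell these explanations apart. No DNA was measured, and an effect of MYT1 on whole arms stays open and untested.

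The mean of MYT1 differed by -20.8% only, while other genes moved far more. Control-like cells, with the shNC profile, left among the shMYT1 cells could lift MYT1, but they would carry the same share of every transcript. That is argued against as the whole cause, since 16 genes had their highest shMYT1 value under 50% of the lowest shNC value. DPT was left at 10.7%. Cells of the shMYT1 culture that kept MYT1 but differed from shNC cells in other genes are not covered by this and stay untested. A mislabelled library is argued against, since 0 libraries lay on the other group's side of MYT1. How far MYT1 protein fell, and whether the hairpin hit other transcripts, was not measured and stays open.

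The shift of neighbouring genes might also account for the gene list calls, through the list members that lie in the shifted segments. This is argued against for 10 of the 11 lists, which stayed past the threshold at the preset correlation without the genes of the shifted segments, though 0 of the 11 pass with an estimated correlation (adjusted p 0.356 to 0.575). The type I interferon list lost its call there, with adjusted p = 0.0512 instead of 0.0192 (0.0108 to 0.191 over the settings with the preset correlation, 0.356 with an estimated correlation and 0.000228 with fry), when 1 strongly raised gene, BST2, was left out and the mean log2 fold change went from 0.24 (SD 0.35, 13 genes) to 0.20 (SD 0.34, 12 genes). BST2 rose by 0.69 on the log2 scale while its segment, the short arm of chromosome 19, shifted down. With the running median of neighbouring genes removed, the list stayed past the threshold at the preset correlation (camera adjusted p = 0.0158). Its mean was then 0.24 (SD 0.36), which argues against the shift as the whole cause of the call. The effect of MYT1 knockdown itself stays open as an explanation of all 11 lists, untested because 1 hairpin label stands for it. A difference between the shNC and shMYT1 cultures apart from MYT1, such as the DNA copy number named above, stays open for them too. Leaving out segment genes takes away only local shifts of at least 0.1, and removing the running median only local shifts. Neither takes away an effect on genes elsewhere. The values cannot separate such a difference from the knockdown.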
